A study of Homo sapiens with 6 samples.

How the data were processed

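RNA was measured by sequencing in 6 libraries of SW1990, an established human pancreatic cancer cell line. Per the labels, 1 library came from the parental line and 1 from a derivative kept in medium with 100 nM gemcitabine, a nucleoside analogue used against pancreatic cancer. The other 4 came from the parental line after flow cytometry: 2 from cells positive and 2 from cells negative for TRA-1-81, a glycan epitope of pluripotent stem cells carried by podocalyxin. Each sorted library has 0603 or 0610 in its title, and these are used as replicate names. The labels do not state what these numbers mark or whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

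The authors deposited 1 table of gene values for the 6 libraries. Its header does not name the unit. The values are taken as deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), because the submitters' processing notes name Cufflinks 2.1.1, which writes that unit, beside TopHat2 2.0.11, CASAVA 1.8.2 and the genome build hg19. The role and settings of each tool are not given in the sources used here. The table has 19312 rows with gene symbol, position and RefSeq identifiers. For the 191 symbols on more than 1 row, the row of highest mean FPKM was kept, which left out 235 rows and kept 19077 genes. No mitochondrial gene is in the table. Positions are given in hg19, with 1 added to the table's starts, because 314 of 345 short olfactory receptor genes had a span divisible by 3 when the start was read as counted from 0.

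Cufflinks shares fragments between transcripts, so read counts could not be recovered and no count model was used. An approximate depth was read from the smallest values of short olfactory receptor genes, where 1 fragment sets the value. Median steps over 3 to 15 genes per library placed 3 fragments on a 1 kb gene at an FPKM of about 0.175 in the parental, 0.145 in the resistant and 0.0974 to 0.111 in the sorted libraries. These are rough values. In 7 genes, exactly 1 library was listed at 0 while the other 5 had an FPKM of at least 5. They include PKM, listed at 0 in the positive library 0603, and APLP2, listed at 0 in the positive library 0610. An exact 0 in this table can therefore be a failed estimate.

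Values were analysed as log2(FPKM + 1), and every log2 change is on that scale, which understates the change of low genes. Positive and negative fractions were compared with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) among the 11533 genes with an FPKM of at least 1 in at least 2 of the 4 sorted libraries, with no covariate. Because the numbers 0603 and 0610 may mark batches, the positive minus negative difference is also given within each number. Resistant and parental cells have 1 library each, so there is no replicate check and no p-value. Genes were counted when the log2 ratio was at least 1 or at most -1, among 12066 genes with an FPKM of at least 1 in either library, and the same rule was applied to other pairs of libraries.

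Before the data were examined, 29 gene lists were fixed, along with the tests, the alternatives and the rule for naming genes. In the sorted fractions, the 24 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, and with an estimated correlation beside it. The test fry was also run, which asks whether a list moves and does not compare it with other genes. In the resistant library, a list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The 2 comparisons, which share no library, were set side by side by their correlation across genes, with no p-value because genes are not replicates. The resistant against parental ratios of the 100 genes with the largest and the 100 with the smallest moderated statistic, moving alike in both numbers, were also compared with matched lists.

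The named genes are the 12 highest and 12 lowest of the sorted comparison past the threshold and alike in both numbers with a mean FPKM of at least 2, filled to 12 by the smallest p where fewer passed. They also include the 12 highest and 12 lowest of the resistant comparison with an FPKM of at least 5 in either library, the 6 highest and 6 lowest over both comparisons, and all gemcitabine genes. PODXL and up to 2 highest and 2 lowest members of each other list complete them. Small RNA genes, unnamed loci and pseudogenes were left out of the first 3 parts. Of these, 1 list member was left out of the text and figures because this build places it on chromosome Y.

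The fits were tested on simulated values for the 11533 genes of the sorted comparison, with 200 genes changed. With a difference between the numbers drawn at the size seen here, the fit without a block recovered 16 of 67 genes changed by 0.5 on the log2 scale, 64 of 67 changed by 1 and 66 of 66 changed by 2, with 0 false calls. The simulation drew normal values with the same spread for all genes of an expression bin, so recovery in the data can be lower. In the data 4 genes were higher by at least 1 in both numbers, and of these only UGT1A6 was called. GPX2, CCL5 and SPRR1B, with log2 fold changes of 1.25, 1.25 and 1.17, were not. Of 100 simulated lists with no shift, 6% fell outside the central 95% of matched lists, and 99% of lists shifted by 1 lay above it. Alternatives covered the pseudocount, the filter on low values, the scaling, the limma variant, the replicate block, the left-out libraries and, chosen after the data were seen, the reference library, repeated symbols, genes listed at 0 and quantile normalization for the lists of the sorted fractions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.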

Results

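The data set holds gene expression of SW1990 pancreatic cancer cells in 6 libraries: 1 parental, 1 of a gemcitabine-resistant derivative kept in 100 nM gemcitabine, and 2 each of TRA-1-81 positive and TRA-1-81 negative cells sorted from the parental line. Between 11164 and 11729 genes per library had an FPKM of at least 1. Log2 values correlated across genes at 0.997 between the positive and negative libraries of the same number (0603 or 0610), at 0.994 between the 2 positive libraries and at 0.992 between the 2 negative ones. The parental and resistant libraries correlated at 0.871. The unsorted parental library correlated with the sorted ones at 0.941 to 0.954, and the resistant library with the sorted ones at 0.912 to 0.932. The resistant library was thus closer to each sorted library than to the unsorted parental one. These correlations leave out 7 genes listed at 0 in a single library, chosen after the data were seen. With them the pairs of the same number gave 0.995, the positive pair 0.990, the negative pair 0.992 and the parental and resistant pair 0.870.

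The first comparison asks how gemcitabine-resistant cells differ from the parental line. The resistant cells were kept in gemcitabine, so resistance and a response to the drug itself cannot be told apart. The genes with the largest ratios included collagenases, keratins and a cornified envelope gene. MMP1, an interstitial collagenase (chromosome 11, 102660641 to 102668966), stood at an FPKM of 0.967 in the parental and 678 in the resistant library. KRT6A, a keratin of activated and stratified epithelium, stood at 3.02 and 1173, KRT17 at 11.03 and 1317 and SPRR1B, a cornified envelope precursor, at 1.61 and 358. The other genes of the largest ratios were IFI27, SPRR2A, BST2, GPX2, CSTA, MMP13, UGT1A10 and C8orf4. Of these, GPX2, a glutathione peroxidase of epithelia, stood at 1.14 and 182 and the collagenase MMP13 at 1.64 and 208.

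Genes lower in the resistant library included CALB2 (calretinin, a calcium-binding protein), with an FPKM of 123 in parental and 0.834 in resistant cells. KLK6, a secreted serine protease, stood at 307 and 6.71, the epithelial transcription factor ELF5 at 36.5 and 0.0761, PSCA (prostate stem cell antigen) at 547 and 21.8 and KISS1, a metastasis suppressor, at 53.03 and 2.51. BPI, TM4SF18, CALHM3 and CPVL were also among the lowest. CAPNS1, the small calpain subunit, was listed at 0 in the resistant library, at 488 in the parental library and at 256 to 293 in the sorted ones, and CACNA2D4 was likewise listed at 0. CAPNS1 is 1 of the 7 genes listed at 0 in a single library, where the 0 can be a failed estimate. RPL21, a ribosomal protein gene with many processed copies, stood at 0.0206 in resistant and 14.97 in parental cells, and is uncertain because reads can be shared with its copies.

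In total, 1629 genes were at least 2-fold higher and 832 at least 2-fold lower in the resistant library. By the same rule, 44 genes were higher and 2 lower between the 2 negative libraries, and 34 higher and 7 lower between the 2 positive ones, taking 0610 against 0603. The median gene had a log2 ratio of 0.09 as deposited and -0.06 after quantile normalization, which gave 1288 higher and 1134 lower genes (53.2% higher, against 66.2%). The sorted parental libraries matter for these counts. Between 603 and 703 genes were at least 2-fold higher in a sorted library than in the unsorted parental one, and 688 genes were at least 2-fold higher and 262 at least 2-fold lower in resistant cells than in each of the 5 parental-line libraries. Whether sorting, culture or a library batch separates the sorted from the unsorted libraries cannot be told apart.

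Genes that handle gemcitabine differed in both directions. DCK, the kinase that activates the drug, stood at an FPKM of 18.2 in parental and 9.57 in resistant cells, below all 5 parental-line libraries (15.8 to 18.2). RRM1, the large subunit of ribonucleotide reductase and a target of the drug (chromosome 11, 4115924 to 4160106), stood at 39.2 and 127, above the other 5 (39.2 to 59.0). CDA, which deaminates the drug, stood at 20.1 and 81.0, above the other 5 (20.1 to 45.8). The nucleoside transporter gene SLC29A1 stood at 9.20 and 25.6 and SLC29A2 at 32.5 and 11.3. NT5E, the ectonucleotidase CD73, stood at 164 and 58.4, and the 5'-nucleotidase NT5C at 56.1 and 22.5. The sorted parental libraries held 14.1 to 18.7 for SLC29A1, 18.7 to 22.2 for SLC29A2 and 108 to 118 for NT5E. For NT5C they held 25.2 to 29.2, close to the resistant value.

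RRM2 stood at 45.1 in parental and 76.4 in resistant cells and SAMHD1, a nucleotide triphosphohydrolase, at 12.5 and 36.1. Both resistant values lay below part or all of the sorted parental libraries, which held 66.5 to 97.2 for RRM2 and 41.9 to 47.2 for SAMHD1. DCK and RRM2 differed by less than 2-fold (log2 ratio -0.86 and 0.75), as did CMPK1, NME1, NME2, TK2, DCTD, NT5C2, NT5C3, RRM2B and TYMS. Of these, RRM2B (-0.88) stood at 8.33 in resistant cells, below all 5 parental-line libraries (13.7 to 19.2). SLC28A1, SLC28A3 and NT5C1A were at an FPKM under 0.05 in every library. Of the 7 measured uptake and activation genes, 1 was at least 2-fold higher (SLC29A1) and 1 lower (SLC29A2). Of the 11 measured inactivation and target genes, 3 were higher and 2 lower. Against the mean of the sorted libraries, only RRM1 (log2 ratio 1.24) and CDA (1.22) of these stayed at least 2-fold apart. There SLC29A1 stood at 0.62, SLC29A2 at -0.76, NT5E at -0.93 and both NT5C and SAMHD1 at -0.29. The list medians of 0.27 and 0.18 lay at percentiles 77.2 and 72.3 of matched lists. Among drug efflux transporters, ABCC5 stood at 7.58 and 66.7, with at most 15.3 in a sorted library, while ABCG2 stood at 11.4 and 2.48 and ABCC1 at 46.9 and 18.9.

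**Figure D1:**
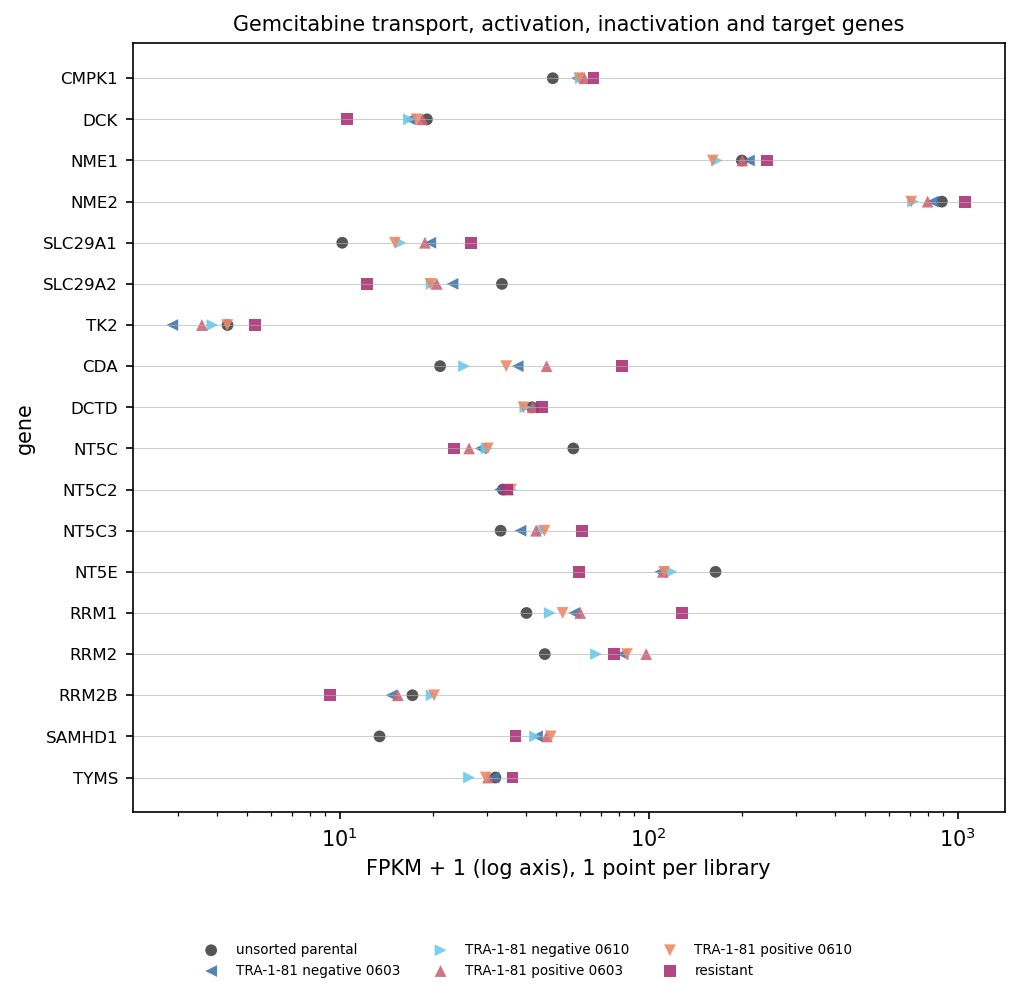
FPKM + 1 on a log axis of the gemcitabine genes with an FPKM of at least 1 in any library, 1 point per library, with no error bars. RRM1 and CDA are highest in the resistant library, at an FPKM of 127 and 81.0, and DCK is lowest there, at 9.57.

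All 24 measured interferon-stimulated genes were at least 2-fold higher in resistant than in unsorted parental cells, with a median log2 ratio of 3.56, above all 10000 matched lists (percentile 100). IFI27 stood at 21.2 and 2841 and BST2 (tetherin) at 4.26 and 458. The sorted parental libraries were also high: IFI27 stood at 1352 to 1453 there and ISG15, picked after its values were seen, at 444 to 630, against 459 in resistant and 42.0 in unsorted parental cells. Against the mean of the sorted libraries, the list's median was 1.02 (percentile 100), and 21 of its members were above all 5 parental-line libraries. Of 19 NF-kB and inflammatory genes, 16 were at least 2-fold higher and 1 lower (median 2.81, percentile 100). CCL20 stood at 6.06 and 153, CXCL1 at 0.668 and 32.1 and PTGS2 (cyclooxygenase 2) at 0.615 and 22.2, whereas LIF stood at 74.6 and 22.4.

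Cholesterol synthesis genes were lower in resistant cells, 6 of 15 by at least 2-fold and 12 of 15 below all 5 parental-line libraries (median -0.90, percentile 0). INSIG1 stood at 114 in parental and 29.0 in resistant cells and MVD at 95.4 and 24.8, while HMGCS1 stood at 50.2 and 99.2. Of 15 unfolded protein and integrated stress response genes, 7 were at least 2-fold lower (median -0.62, percentile 0.035). ASNS, asparagine synthetase, stood at 295 and 24.96 and the pseudokinase gene TRIB3 at 108 and 8.47. These genes also separated the sorted libraries by number: ASNS stood at 19.3 and 21.1 in the 0603 libraries and at 86.7 and 86.8 in the 0610 libraries.

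Mesenchymal genes had a median log2 ratio of 0.98 (percentile 99.8), with 5 of 10 at least 2-fold higher and 1 lower. SNAI2, a repressor of epithelial genes, stood at 9.39 and 104 and FN1 (fibronectin) at 6.44 and 58.4, while S100A4 stood at 1653 and 378. The sorted parental libraries held 13.0 to 20.9 for SNAI2, 2132 to 2877 for S100A4 and 29.5 to 55.7 for FN1. Against their mean the log2 ratio of FN1 was 0.58 and the mesenchymal list's median was 0.50 (percentile 98.7). Mucin and ductal secretory genes had a median of 1.56 (percentile 99.99), with 7 of 12 at least 2-fold higher and 2 lower, CEACAM6 among the higher at 50.2 and 347. Against the sorted libraries the mucin list's median was -0.54 (percentile 0.12), so its direction depended on the reference, with 1 member above and 4 below all 5 parental-line libraries. NRF2 target genes (median 0.57, percentile 99.1), Notch pathway genes (0.99, percentile 99.6), Wnt target genes (0.89, percentile 97.8) and immediate early and heat shock genes (0.83, percentile 99.9) lay above the matched lists. Mitosis genes (-0.39, percentile 0.46) and cytosolic ribosomal protein genes (-0.45, percentile 0.65) lay below them. The ribosomal protein list lay within the central 95% after quantile normalization (percentile 4.11), as did the Wnt list (96.7), which also did with a pseudocount of 5 (95.1), as did the Notch list (93.0).

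The immediate early gene FOS stood at 5.49 in parental and 2.96 in resistant cells and at 53.9 to 63.0 in the sorted libraries. Of the 12 lists outside the central 95% of matched lists, 6 stayed outside it on the same side against the sorted libraries and the mucin list lay on the other side. The Notch, Wnt, immediate early, mitosis and ribosomal protein lists lay within it. The other 13 lists with at least 5 measured members lay within the matched lists, among them p53 targets (median 0.21, percentile 76.5), DNA damage genes (0.29, percentile 89.7), stem cell markers (0.41, percentile 89.9) and epithelial genes (-0.27, percentile 5.70). Against the sorted libraries 5 of these 13 lay outside: epithelial genes (-0.53, percentile 0.02), p53 targets (-0.28, 1.93) and TRA-1-81 carrier and synthesis genes (-0.40, 2.06) below, and stem cell markers (0.62, 99.04) and histone genes (0.48, 98.4) above. Of 19 p53 targets, 3 were at least 2-fold higher and 2 lower, with CDKN1A, the p21 cell cycle inhibitor, at 7.67 and 88.0 and BTG2 at 0.569 and 21.0.

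**Figure D2:**
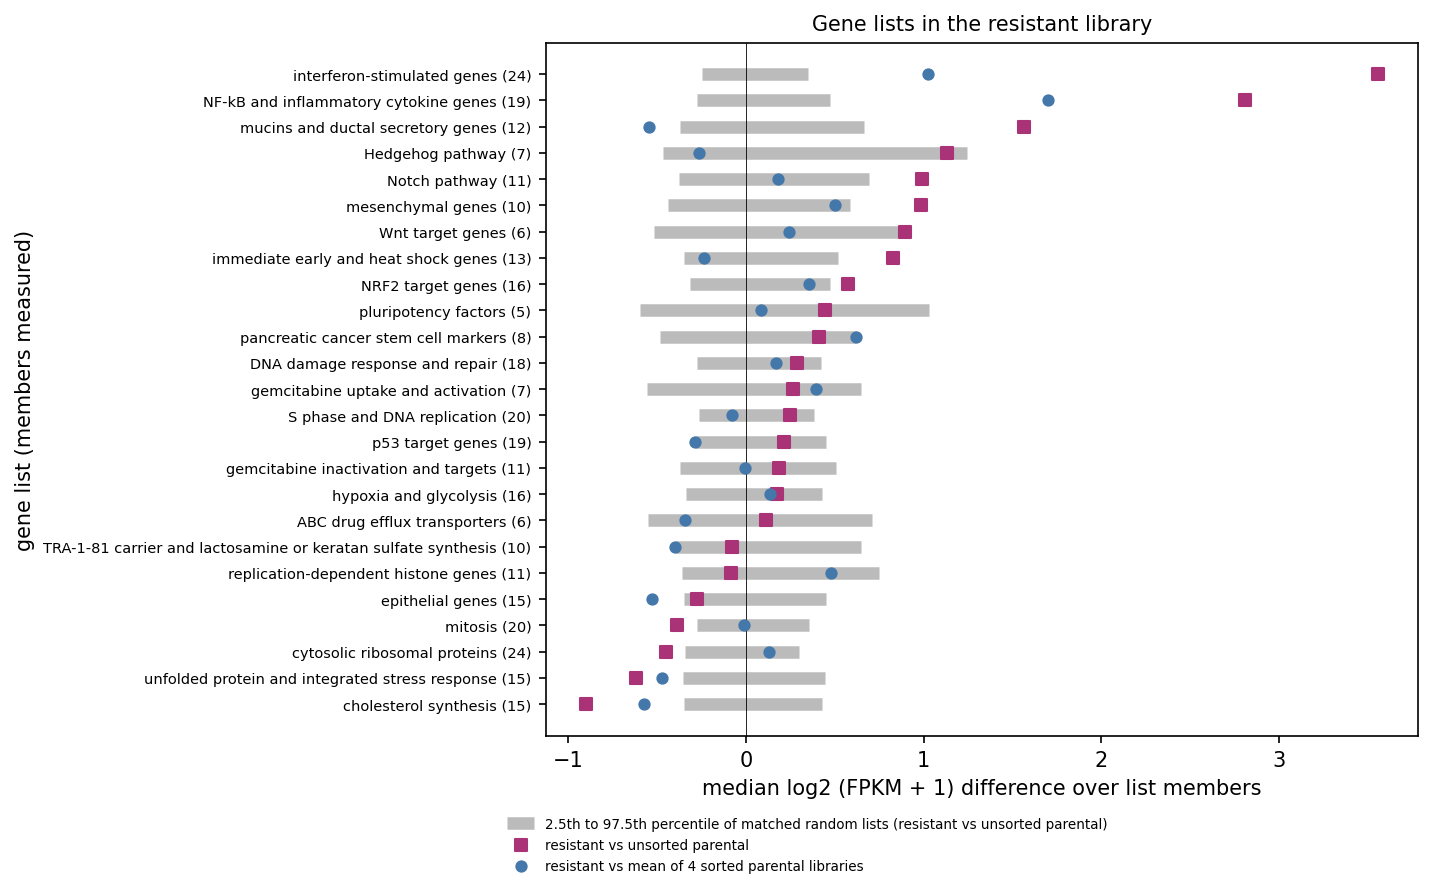
Median log2 (FPKM + 1) difference of each fixed gene list, resistant against the unsorted parental library (squares) and against the mean of the 4 sorted parental libraries (circles), with grey bars for the central 95% of matched random lists of the first comparison. Interferon-stimulated genes lie at 3.56 and 1.02, and mucin genes move from 1.56 to -0.54.

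The second comparison asks which genes differ between TRA-1-81 positive and negative cells of the parental line. UGT1A6, a glucuronosyltransferase (chromosome 2, 234600321 to 234681951), was the 1 gene past the threshold in the fit with no term for the numbers. Its FPKM was 6.53 ± 0.236 (SD, n = 2) in positive and 0.641 ± 0.0321 (SD, n = 2) in negative cells, a log2 fold change of 2.20 ± 0.08 (SE; limma adjusted p = 0.0295). It did not pass with no filter on low values (0.173), with an FPKM of at least 5 (0.0825) or with quantile normalization (0.0501), over a range of 0.00336 to 0.173 in the settings with no term for the numbers. The difference was 2.21 within 0603 and 2.19 within 0610. The UGT1A genes share their last exons, so UGT1A6 cannot be told apart with certainty from UGT1A10 and the other members. The resistant library held 55.5 and the unsorted parental library 0.000288, below both fractions sorted from that line. So low a value can reflect how fragments were shared between the UGT1A genes, and the ratio to the parental library is uncertain. Against the mean of the sorted libraries the log2 ratio of UGT1A6 in resistant cells was 4.01.

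The next genes by p did not pass the threshold, but were higher in positive cells within both numbers. KRT17 stood at 167 ± 5.14 in positive and 92.1 ± 1.30 in negative cells (SD, n = 2 each), a log2 difference of 0.87 within 0603 and 0.83 within 0610 (limma adjusted p = 0.30). GPX2 stood at 38.2 ± 3.87 and 15.5 ± 1.09, a difference of 1.21 and 1.28 (limma adjusted p = 0.30). TRIM29, a protein of basal epithelial cells, stood at 10.0 ± 0.107 and 5.14 ± 0.102, a difference of 0.82 and 0.87. GLUL (glutamine synthetase), PI3 (elafin), FAT2, ZNF385A, INPP5D, DUSP9, IFIT2 and SPRR1B followed, with log2 fold changes of 0.61 to 1.17 and limma adjusted p of 0.487.

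The 12 named genes with lower values in positive cells had log2 fold changes of -0.78 to -0.31 and limma adjusted p of 0.487 to 0.589. ELF5 stood at 3.37 ± 0.674 in positive and 6.44 ± 0.0350 in negative cells (SD, n = 2 each) and SCG2, a secretogranin, at 37.1 ± 4.77 and 59.5 ± 6.44. DCLK1, a kinase used as a tuft and stem cell marker, stood at 6.22 ± 0.320 and 9.29 ± 0.683, with the connexin gene GJA5 at 11.9 ± 0.170 and 16.6 ± 0.211. The others were SLCO4A1, NR1H3, MMP2, HAPLN1, BDNF, CPVL, WDR54 and HS6ST1.

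**Figure D3:**
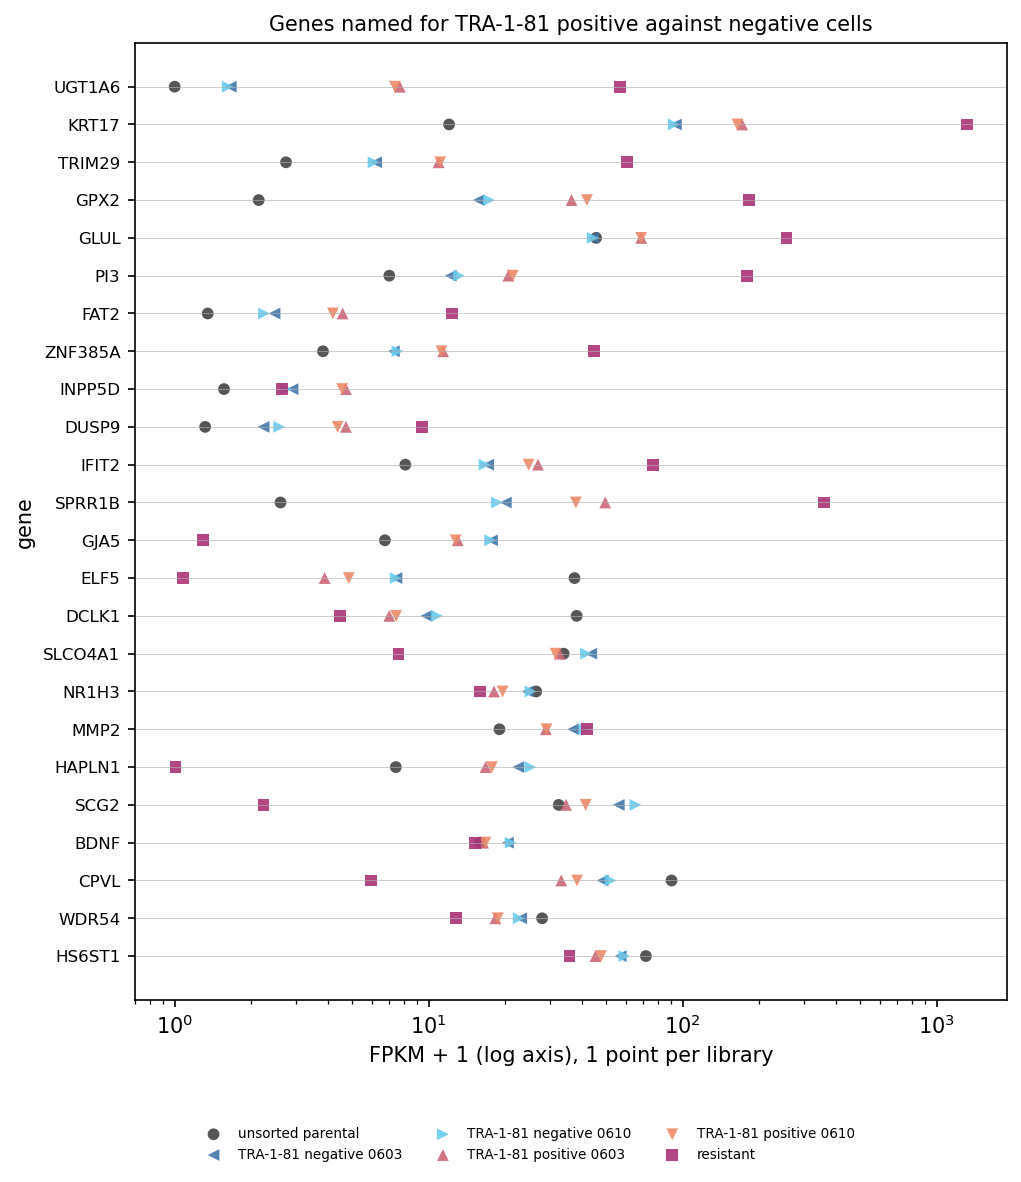
FPKM + 1 on a log axis of the 24 genes named for TRA-1-81 positive against negative cells, 1 point per library, with no error bars. UGT1A6 stands at an FPKM near 6.53 in the positive, 0.641 in the negative and 55.5 in the resistant libraries.

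PODXL, which encodes podocalyxin (chromosome 7, 131185021 to 131241376), stood at 108 and 109 in the positive and 104 and 110.3 in the negative libraries, a log2 fold change of 0.02 ± 0.07 (SE) that did not pass the threshold. It stood at 153 in the parental and 71.7 in the resistant library. Of the pluripotency factors, 5 of 14 were tested and 0 passed, also when adjusted over the list alone. KLF4 had a fold change of 0.40 ± 0.32 (SE) on the log2 scale, and POU5F1 stood at 1.98 ± 0.0364 in positive and 1.72 ± 0.183 in negative cells (SD, n = 2 each).

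By camera with a preset correlation 5 of 24 lists differed from other genes, and 0 with an estimated correlation. By fry, which tests whether a list moves and not whether it differs from other genes, 0 passed. Interferon-stimulated genes were higher in positive cells (median log2 fold change 0.28, limma-based camera adjusted p = 3.33e-16, and 0.374 with an estimated correlation), with 0 of 23 tested members past the threshold over all genes and 9 adjusted over the list alone. OASL stood at 34.3 ± 6.12 and 16.9 ± 0.976 (SD, n = 2 each) and RSAD2 (viperin) at 21.7 ± 1.93 and 13.4 ± 1.68. Mitosis genes were higher (median 0.23, camera adjusted p = 2.40e-12, and 0.763 estimated), 20 of 20 within both numbers and 0 past the threshold either way, with CDK1 at 176 ± 4.39 and 141 ± 1.91. Mucin and ductal secretory genes were higher (0.19, camera adjusted p = 0.00435, and 0.763 estimated), with 1 of 12 past the threshold over the list alone and MUC4 at 4.96 ± 0.605 and 2.54 ± 0.0858. That list was also lost without the negative library 0603 (camera adjusted p = 0.102) or the positive library 0610 (0.459).

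Cytosolic ribosomal protein genes were lower in positive cells (median -0.12, camera adjusted p = 8.07e-12, and 0.763 with an estimated correlation), 24 of 24 within both numbers, with RPS3 at 1449 ± 2.16 and 1654 ± 19.5 (SD, n = 2 each). After quantile normalization, a setting added for lists after the data were seen, the ribosomal median was -0.04 (camera adjusted p = 0.0496). Mesenchymal genes were lower (-0.13, camera adjusted p = 0.0315, 0.763 estimated, 0.0523 after quantile normalization and 0.227 without the negative library 0610), 9 of 11 within both numbers, with 1 past the threshold over the list alone. MMP2 stood at 27.999 ± 0.105 and 38.0 ± 2.75, while SNAI2 had a log2 fold change of 0.40. Over the list alone, 2 NRF2 targets, AKR1B10 and AKR1C2, were higher, and among stem cell markers 1 was higher and 2 were lower. In the acinar and endocrine marker list 1 gene of 3 tested, CEL, was higher.

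Over all genes limma called 1 gene higher and 0 lower, and 421 higher and 144 lower at an unadjusted p under 0.05. This fit has no term for the numbers, so the difference between 0603 and 0610 stays in the spread it tests against. The count of 1 is therefore no measure of how little the fractions differ, and the counts with such a term are given under the processing. Without the positive library 0603 or 0610, UGT1A6 did not pass the filter on low values and 0 genes were higher, with 3 and 1 lower, and without the negative library 0610 3 were higher. Within the numbers, the positive minus negative difference correlated across genes between 0603 and 0610 at a Pearson r of 0.418 and a Spearman rho of 0.543. Without the 7 genes listed at 0 in 1 library, an exclusion chosen after the data were seen, r was 0.633. It was at least 0.5 on the log2 scale upwards in both numbers for 68 genes, downwards in both for 12, and opposite for 3.

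The third comparison asks whether genes that differ between resistant and parental cells differ in the same direction between the sorted fractions. Across 11407 genes the 2 sets of log2 changes correlated at a Pearson r of 0.397 and a Spearman rho of 0.318, with r of 0.350 for the 0603 pair and 0.319 for the 0610 pair. The 100 genes highest in positive cells had a median resistant against parental log2 ratio of 2.86, above all 10000 matched lists, and 85 of them were at least 2-fold higher in resistant cells and 1 lower. The 100 genes lowest in positive cells had a median of -0.94, below all 10000 matched lists, with 46 at least 2-fold lower and 7 higher. With no filter on low values these medians were 0.98 and -0.037, still at percentiles 100 and 0. All these ratios use the 1 unsorted parental library, from which the negative libraries also differed. Across genes, the positive minus negative change correlated at a Pearson r of 0.293 with the sorted minus unsorted parental change. Part of the overlap may therefore be shared with the difference between sorted and unsorted libraries.

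The genes with the largest changes shared by both comparisons were UGT1A6, the chemokine gene CCL5, GPX2, SPRR1B, KRT5 and SLC2A9. KRT5, a basal keratin, stood at 240.0 ± 32.1 in positive and 119 ± 18.9 in negative cells (SD, n = 2 each), and at 24.1 in parental and 1201 in resistant cells. CCL5 stood at 14.03 ± 1.70 and 5.35 ± 1.27, and at 1.87 and 18.1. In the other direction were, among others, ELF5, SCG2, VCAN (versican) and BPI. VCAN stood at 10.5 ± 0.883 and 17.3 ± 3.28, and at 26.3 in parental and 11.1 in resistant cells. Not all genes of the resistant library followed: MMP1 had a log2 difference of 0.15 within 0603 and -0.07 within 0610. Of the lists that camera called between the fractions, the interferon, mucin and ribosomal lists moved alike in both comparisons. Mesenchymal genes ran opposite (median 0.98 in resistant and -0.13 in positive cells), as did mitosis genes (-0.39 and 0.23). This holds with the unsorted parental library as reference. Against the sorted libraries the interferon (1.02) and mesenchymal (0.50) medians kept their sign in resistant cells. There the mucin (-0.54) and ribosomal (0.13) medians changed sign, and the mitosis median was -0.008.

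**Figure D4:**
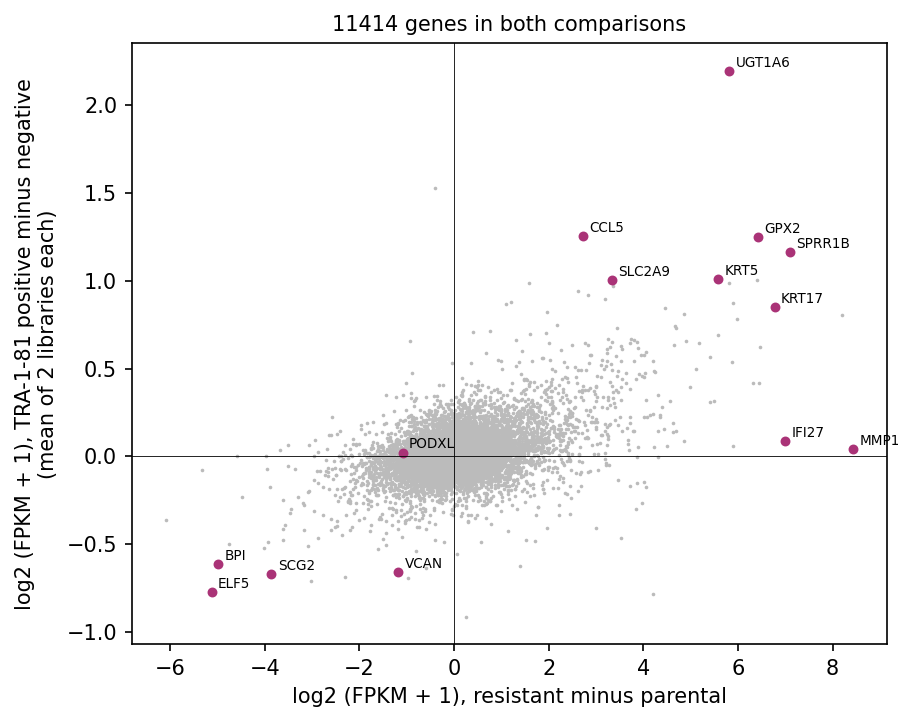
Each point is 1 gene, with the log2 (FPKM + 1) difference of resistant minus parental on the x axis and of TRA-1-81 positive minus negative on the y axis (means of 2 libraries each), leaving out the 7 genes listed at 0 in 1 library, genes placed on chromosome Y and XIST. It draws 11414 genes, a set that differs from the 11407 genes of the correlation. UGT1A6 lies at 5.82 (with a parental FPKM of 0.000288) and 2.20, and MMP1 at 8.43 and 0.04.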

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

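Settings on repeated symbols, genes listed at 0, other reference libraries and quantile normalization for the lists of the sorted fractions were chosen after seeing the data. The replicate block, with the numbers 0603 and 0610 as a term, gave 919 genes higher and 565 lower in TRA-1-81 positive cells against 1 and 0 without it, and 8 lists by camera against 5. On simulated data with the number difference as seen, the block recovered all changed genes (67 of 67, 67 of 67 and 66 of 66) with 12 false calls. The simulation gave all genes of an expression bin the same spread, so these figures may not hold for the data. The 0610 minus 0603 difference correlated across genes at 0.654 between the 2 fractions, and at 0.825 without the 7 genes listed at 0. The labels do not say that the number marks a shared sort or day and there are 2 pairs, so the block was kept as an alternative. These correlations show that libraries of the same number share variation, which the fit without the block leaves in its spread. With no filter, with an FPKM of at least 5 or with quantile normalization, 0 genes were higher, and the limma adjusted p of UGT1A6 was 0.173, 0.0825 and 0.0501, against 0.00336 to 0.0350 in the settings without a block that called it. Leaving out each sorted library gave 0 to 3 genes higher, 0 to 3 lower and 9 to 12 lists. Of these, 4 lists not called with all libraries passed in opposite directions depending on the library left out: the S phase, NF-kB, p53 and stress response lists. There, the lone library of a fraction is assumed to vary like the others. With an estimated correlation 0 lists passed, and with fry 0. After quantile normalization 5 passed, with the mesenchymal list (camera adjusted p = 0.0523) lost and the immediate early list gained.

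In resistant cells, a pseudocount of 5 gave 777 genes higher and 397 lower. With the sorted parental libraries as reference 995 were higher, and with the nearest of the 5 parental-line libraries 688 were higher and 262 lower. Against the sorted libraries the log2 ratio of SAMHD1 was -0.29, and the medians of the immediate early, mucin and ribosomal protein lists changed sign, to -0.24, -0.54 and 0.13. The cause was not tested, except that a larger pseudocount shrinks low genes and the nearest library is by construction the strictest reference.

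The Pearson r between the comparisons was 0.374 with a pseudocount of 0.1, 0.458 without the genes listed at 0, and 0.319 to 0.350 with 1 number left out. The Spearman rho was 0.280 with no filter and 0.276 to 0.297 with 1 number left out. The median ratio of the 100 highest genes was 3.43 with a pseudocount of 0.1, 1.73 with 5, 0.98 with no filter, and 2.86 to 3.23 with 1 number left out. That of the 100 lowest was -0.58 with a pseudocount of 5, -0.037 with no filter, -1.14 with quantile normalization and -1.02 to -0.86 with 1 number left out. The cause was not tested. For these counts, correlations and medians, 62 further values kept within 1.5 times the count or within the spread. For single genes and the 19 lists with a median in the text, 576 values were the same, 155 moved, 26 newly passed a threshold or left the range of matched lists, 24 no longer did, and the 4 above changed sign. Lists within the matched lists were not counted for sign, and the p53 median turned negative (-0.28) with the sorted reference. Genes near 0.175 FPKM or below rest on few fragments.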

Other observations

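All groups and tests here, apart from the fixed gene lists, were chosen after the results were seen. Keratinocyte and squamous epithelium genes, a group of 27, were higher in resistant cells: 24 of 26 measured by at least 2-fold and 25 above all 5 parental-line libraries (median 3.53, percentile 100 of matched lists). Because this group was picked after the results were seen, the percentile is no test of it. In the sorted fractions 23 of 23 were higher in positive cells within both numbers (median log2 difference 0.67 within 0603 and 0.62 within 0610). TP63, the regulator of basal epithelium, stood at an FPKM of 0.206 in parental, 34.2 in resistant, 7.43 ± 1.02 in positive and 3.84 ± 1.06 in negative cells (SD, n = 2 each). COL17A1, a hemidesmosome collagen, stood at 3.94, 236, 60.0 ± 5.33 and 36.8 ± 2.99.

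HLA class I and antigen processing genes were higher in positive cells within both numbers in 16 of 16 genes (median 0.34 and 0.36), and 13 of 16 were at least 2-fold higher in resistant than unsorted parental cells (median 1.98). Against the sorted libraries the median was 0.49 (percentile 99.7, again no test of a group picked afterwards), and 12 of 16 were above all 5 parental-line libraries. HLA-B, which presents peptides to T cells, stood at 31.1 in parental, 957 in resistant, 503 ± 46.5 in positive and 320 ± 55.2 in negative cells (SD, n = 2 each). The HLA class I genes are near-identical copies, so their single values are uncertain.

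The first pattern is that genes high in resistant cells were higher in the positive fraction. A single share of cells with the resistant profile among the positive cells would give each gene the same implied share. Over 57 genes at least 8-fold higher in the resistant library than in the negative fraction, it had a median of 2.25% within 0603 (quartiles 0.936% and 4.84%) and 1.56% within 0610 (quartiles 0.285% and 4.60%). Genes 8-fold lower in resistant than in parental cells implied a larger share, a median of 21.3% within 0603 (24 genes, quartiles 15.7% and 34.9%) and 22.2% within 0610 (29 genes, quartiles 6.40% and 27.8%). Their count differs between the numbers, so the sorted libraries also entered their choice, which may bias the share. A single share as the whole pattern is therefore not settled. The other of the 4 tests tried do not decide it: 24.6% of genes lay under 0.5 times the median share (bound 25%), and a Spearman rho of 0.849 was between shares that use 1 resistant library. A choice of 18 genes on the positive fraction, which biases the share downwards, gave medians of 13.3% and 12.2%. Their lower quartiles of -2.66% and -1.49% lay below the upper quartiles of the 57 higher genes. The relation stayed at a Pearson r of 0.398 among genes with an FPKM of at least 5, which argues against low genes as its source. What stays open, as hypotheses, is a share of resistant-like cells or an expression state partly shared with the resistant line. The 100 lowest genes lay at percentile 0 of matched lists, but either would lower them, so this does not tell them apart.

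The second pattern is that the 4 sorted parental libraries lay between the unsorted parental and the resistant library for many genes (Pearson r 0.675 across genes between both differences from the parental library, which share that library and so correlate in part by construction). A single share of resistant cells as the whole pattern is argued against, since among 173 genes at least 8-fold higher in resistant than in parental cells 18 interferon-stimulated genes implied a median share of 35.3% to 48.3% and the other 155 of 8.68% to 14.5%, with the lower quartile of the first above the upper quartile of the second by at least 4.65 percentage points in all 4 libraries. This was 1 of 5 tests tried. It was chosen after the interferon-stimulated genes were seen to be high in the sorted libraries, so it describes these genes and is no independent test. In all 4 sorted libraries 59 genes lay 2-fold above both the unsorted and the resistant library (against 23 and 0 between the numbers). A mix alone would not place genes above both, but this says nothing on genes that lie between. Among the 59 is PLEC, listed at 0 in the parental and resistant libraries and at 137 to 160 in the sorted ones, where the 0 can be a failed estimate. RAD23B was listed at 0 in all 4 sorted libraries and at 65.8 and 58.7 in the parental and resistant ones. The 23.1% of genes under 0.5 times the median share (bound 25%), a Spearman rho of 0.9005 between shares that use the same libraries, and 15 lower genes (medians -43.0% to -7.37%, quartiles -94.2% to 63.5%) decide nothing. Library scaling is argued against, since after median-ratio rescaling at least 566 genes were 2-fold higher in each sorted library than in the unsorted one, against 43 and 28 between libraries of 1 fraction. Flow sorting, a separate culture of the sorted cells and a library batch cannot be told apart, since no sorted and unsorted libraries share a number. Of a library batch, only scaling was tested. The 0 listings of PLEC and RAD23B set the parental and resistant libraries together apart from all 4 sorted ones. The approximate depth of those 2 libraries was also lower than that of the sorted ones. Immediate early and heat shock genes lay at percentile 100 in sorted against unsorted cells, which does not separate sorting, culture and batch.

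The third pattern is the difference between numbers 0603 and 0610. Unfolded protein and integrated stress response genes were higher in 0610 by a median of 0.53 in positive and 0.54 in negative cells, and S phase genes lower by -0.32 and -0.46. Library scaling is argued against, since the smaller of the 2 stress list medians was still 0.51 after rescaling. A culture or library batch marked by the number is consistent with the r of 0.825 across genes between the fractions (0.654 with the 7 genes listed at 0). No biological explanation was tested, since the labels give none.

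In 7 genes, 1 library was listed at 0, and others such as PLEC and RAD23B were listed at 0 in more than 1 library. RAD23B is among the 57 genes of the implied share above. PKM, a glycolytic enzyme gene, was listed at 0 in the positive library 0603 and at 1139 to 1414 in the others. APLP2, an amyloid precursor-like protein gene, was listed at 0 in the positive library 0610 and at 201 to 349 in the others.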
